A study of Mus musculus with 12 samples.

How the data were processed

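Total RNA from triceps muscle sections was turned into biotin-labelled cRNA and measured on 1-channel arrays, per the labels, with 1 array per sample. The array platform and the scanner processing are not given in the sources used here. The deposited table gives 1 intensity per feature and array on a linear scale, already normalized by the authors. The sorted values of all 12 arrays were compared: at most 1.20% of them differed by over 0.01 from those of the first array, so the arrays share 1 distribution. Array medians on the log2 scale differed by 0.000326, under the limit of 0.25 set for renormalizing, and no further normalization was applied. The smallest value on each array is 0.001. This floor was read from the values, since its meaning is not given in the sources used here. It makes up 3718 values, or 0.855%, in 2168 features.

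Row identifiers run from 1 to 36227 without a gap. Although 5896 of these numbers also occur as gene numbers in the annotation, a run without gaps is a row count, and no gene was assigned. Choices that need gene names could not be run: the 38 gene lists fixed beforehand, the check of Gne itself, 1 feature per gene, and a sex term from sex-linked genes. Each feature was tested on its own.

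Samples were grouped by the genotype label into GNE myopathy model (n = 9) and control littermate (n = 3). No label gives a batch, sex or age. Each sample title ends in its own number, which was taken as 1 animal per array, so p-values rest on the spread between animals. Titles of the model arrays also carry the word reanalysis and those of the littermates do not; what it refers to is not given in the sources used here. The number of arrays, 3 in the smaller group, limits the precision.

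The main test, with its 12 arrays and no covariates, was chosen before the data were examined. Intensities were transformed as log2 of the value plus 16. Features with a mean under the 40th percentile (log2 of 4.82) were left out as dim, which removed 14491. The rest were compared by limma (lmFit and eBayes with a trend, two-sided), and calls were made at a Benjamini-Hochberg adjusted p under 0.05. A fold is on the scale with 16 added. Separation of the groups was tested by a pseudo-F on distances between arrays, with exact enumeration of the 220 splits of the arrays into 9 and 3. Spread was described by the median SD per feature. R 4.3.3, limma 3.58.1, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

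The main test was tested on simulated data with 9 and 3 arrays and 21736 features, of which 200 were changed. It found 44.8% of changes of 0.5 on the log2 scale, 86.6% of changes of 1 and 100% of changes of 2. Of 162 calls 8, or 4.9%, were false. The simulated noise was independent between features and arrays, with the same spread in both groups and no floor values. Real arrays need not behave this way, so these rates may not hold for them.

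The rule for named genes asked for Gne and the 10 largest rises and falls among called genes without overlap between groups. Since rows have no gene names, only 2 features per direction are named. The largest falls by the rule are floor features. The named falls, the largest among called features above the floor, were therefore chosen after their values were seen. Feature 16116 was also chosen after its values were seen. Alternatives planned beforehand were quantile normalization, other filters and pseudocounts, limma without trend or with robust fitting, array weights, separate group spreads, a 2-fold minimum, an exact permutation test per feature and leaving out each array. Leaving out floor features and setting floor values to missing were chosen after seeing the data. In the latter, features were kept with at least 4 model and 2 littermate values. The array sets as a random block, combinations of these choices with weights or left-out arrays, and the separation under other settings were chosen then too. The sets were the genotype groups, and an array with many features above the floor on it alone was made its own set. All samples and columns were used.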

Results

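RNA from triceps muscle of mice was hybridized to 12 arrays, 9 from a mouse model of GNE myopathy and 3 from control littermates. GNE is the enzyme that starts sialic acid synthesis, and GNE myopathy is an inherited muscle disease caused by mutations in its gene. The model mice lack their own Gne and carry a transgene with a mutated GNE, and the littermates keep a copy of Gne beside the transgene. All 12 animals were untreated, so the N-acetylcysteine treatment that the series names could not be examined here. The table holds normalized intensities for 36227 array features, and the 21736 brightest were tested. Features are identified in it by row number alone, and nothing used here pairs those numbers with genes. The values below therefore describe features, and no gene or pathway can be named.

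The comparison of model with littermates asked which transcripts differ in muscle that makes GNE from the mutated transgene alone. At an adjusted p under 0.05 in limma, 20 features differed, 3 higher and 17 lower in the model. Of the 17 lower features, 14 were listed at the table's smallest value, 0.001, on 8 or 9 of the 9 model arrays, so these rest on a floor value whose meaning is not given in the sources used here. The other 6 were above the floor on every array, and in each of them every model array lay on one side of every littermate array.

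Feature 31720 had the largest rise among the called features. Its intensity was 58.0 ± 15.3 (SD, n = 9) in the model and 17.8 ± 1.74 (SD, n = 3) in littermates. The difference on the log2 scale, after 16 was added to each intensity, was 1.10 ± 0.16 (SE), with an adjusted p of 0.00961 in limma. Feature 7890 was a bright feature, at 1532 ± 327 (SD, n = 9) in the model and 779.6 ± 49.4 (SD, n = 3) in littermates. It was higher by 0.93 ± 0.16 (SE) on the log2 scale, with an adjusted p of 0.0397 in limma.

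Feature 35231 had the largest fall among called features above the floor. Its intensity was 67.5 ± 20.3 (SD, n = 9) in the model and 161.1 ± 22.4 (SD, n = 3) in littermates. It fell by 1.11 on the log2 scale (SE 0.19), with an adjusted p of 0.0397 in limma. Feature 1464 had an intensity of 38.1 ± 7.27 (SD, n = 9) in the model and 72.2 ± 8.76 (SD, n = 3) in littermates. It fell by 0.71 on the log2 scale (SE 0.12), with an adjusted p of 0.0380 in limma. The remaining pair of called features above the floor changed less, one up by 0.51 and one down, with a log2 difference of -0.50 between model and littermates.

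**Figure D1:**
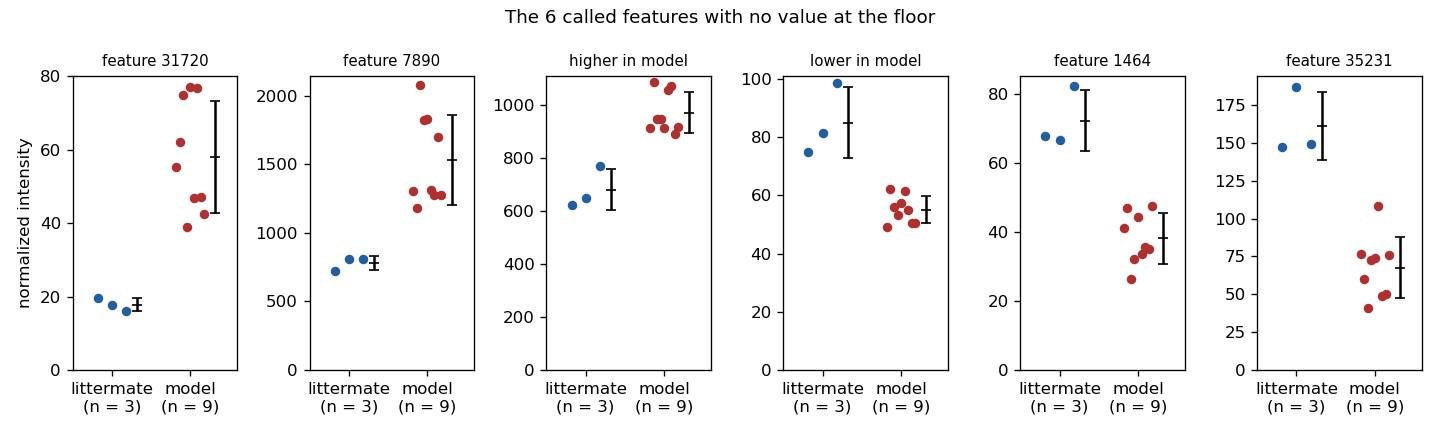
Normalized intensity (linear axes from 0) of the 6 called features that were above the floor on every array. Each point is 1 array, and the bar beside each group is its mean with the SD (littermate n = 3, model n = 9); the groups do not overlap in any panel.

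In the unweighted test these 6 calls depended on the floor features being included. When every feature with a floor value on any array was left out, 21550 features remained and limma called 0 of them. The smallest adjusted p was then 0.117, for feature 31720, and the 5 others each had 0.139. Their log2 differences did not move. With floor features kept, leaving out any 1 littermate ended the calls of all 4 named features, with adjusted p in limma from 0.0570 to 0.313. The 14 floor features have very small p-values, and the Benjamini-Hochberg step lets more features pass when they are counted. Among the 21550 features with no floor value, 2129, or 9.88%, had an unadjusted p under 0.05 in limma, 942 higher and 1187 lower in the model. On those 21550 features limma called 69, 38 higher and 31 lower, when each array was weighted by its scatter, and 4 when each group had its own spread. All 4 named features were called in both, with adjusted p in limma of 0.0267 each with array weights, and of 0.0298 for feature 31720 and 0.0449 for the others with separate spreads. An exact permutation test per feature over all 220 splits of the arrays called 0, with 1928 features at an unadjusted p under 0.05; the smallest adjusted p it reached was 0.344.

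Most differences between the groups were small. The median absolute log2 difference over the tested features was 0.096, against a median standard error of 0.11. Among features above the floor on every array, 36 were at least 2-fold higher and 2 at least 2-fold lower in the model, and of these 1 in each direction was called. Every model array lay above every littermate array in 258 tested features and below in 345. Together these were 603 features, or 2.77%, where a random split of the arrays gives 0.909% on average. Above the floor on every array the count was 585, and the split that sets models 3, 4 and 8 apart gave 976.

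The floor features that were lower in the model fell into levels. In 8 of the 14 the littermate intensity was 1787 ± 90.7 (SD of the 3 arrays). Of the 72 model values 71 were at the floor, and the remaining value was 3.32. In the other 6 it was 223.6 ± 16.8 (SD of the 3 arrays), and all 54 model values were at the floor. The 8 bright ones lay in 4 runs of neighbouring rows that were picked out for similar, bright and nearly constant values. The 119 features of those runs with no floor value had a median intensity of 1600 on model arrays and 1581 on littermate arrays. No fold is given for these features.

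**Figure D2:**
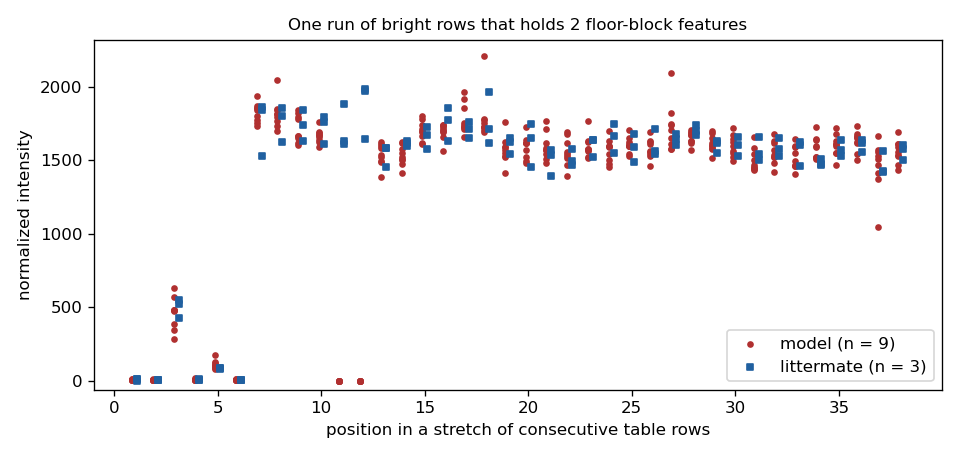
Normalized intensity (linear axis) of 38 consecutive rows of the table, of which a run of bright features starts at position 7. Each point is 1 array (model n = 9, littermate n = 3). At positions 11 and 12 all model arrays are at the floor. The rest of the run is bright in both groups, which the choice of runs by nearly constant values favours.

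On the 21550 features above the floor, the pair of arrays with the highest correlation across features (r = 0.988) was littermate 1 with littermate 2. The lowest (r = 0.960) was model 7 with model 8. The mean correlation across features was 0.978 over the 36 pairs of model arrays, 0.985 over the 3 pairs of littermates and 0.978 over the 27 pairs between groups. Features are not independent replicates. The first principal component held 23.3% of the variance, and the 3 littermates lay above 8 of the 9 model arrays on it and below model 8. On the second, with 17.5%, littermates 2 and 3 lay above every model array, at 9.90 and 20.6 against 9.23 for the highest model array, and littermate 1 lay among the model arrays at 6.81. Between-group distance relative to within-group distance gave a pseudo-F of 1.62, with an exact permutation p of 0.0409 over 220 splits of the arrays. Another split gave a pseudo-F of 2.09. With the floor features included it was 2.64, with an exact permutation p of 0.00455, the smallest that 220 splits can give. The p of the separation above the floor was 0.05 or more without model 2 (0.0727), model 4 (0.0788), littermate 1 (0.164), littermate 2 (0.164) or littermate 3 (0.127), all exact permutation values. With an array left out fewer than 220 splits remain, and fewest without a littermate. These values are therefore coarser than the p from all arrays and not directly comparable with it.

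**Figure D3:**
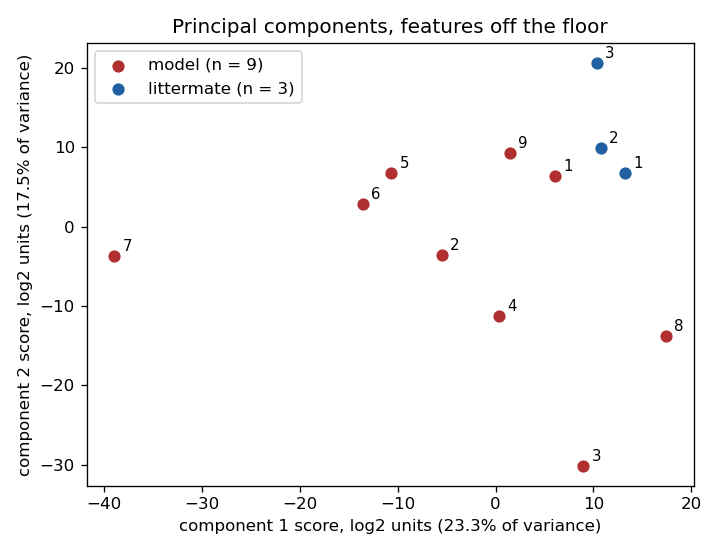
Principal component scores (log2 units) of the 12 arrays on the 21550 features above the floor, with component 1 (23.3% of the variance) across and component 2 (17.5%) up. Each point is 1 array with its replicate number; model 7 lies lowest on component 1 at -39.0, and the 3 littermates lie between 10.36 and 13.3, above all model arrays but model 8. On component 2 littermates 2 and 3, at 9.90 and 20.6, lie above every model array.

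Model arrays differed more among themselves than littermates did. The median SD per feature on the log2 scale was 0.171 in the model (n = 9) and 0.122 in littermates (n = 3). With 3 arrays on both sides the difference was smaller: over the 84 possible trios of model arrays the median SD ranged from 0.117 to 0.177, with a median of 0.147. In 2 of the 84 trios it was below that of the littermates.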

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

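The tests of the floor features, the counts over all 220 splits, and the counts over other splits for all called features and for those above the floor, were chosen after the result was seen; the other tests were written before their values were known, the one that leaves out each model array after the component shares had been seen.

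Model 7 had 215 features at least 2-fold from the median of the model arrays, 207 above and 8 below; the next array, model 3, had 112. Model 9 had 401 values at the floor, and the next model array had 322. Both were singled out because the gap to the nearest of the other model arrays was large against the range of the group. Of 11 measures tested this way 2 stood out, and chance gives about 1 in 20.

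In 18 features at least 8 of the 9 model arrays were at the floor while no littermate was; 14 of them passed the test as lower and 4 were too dim to be tested. A signal that sank only to the level of the dimmest measured features is argued against for these 18. Among the 3542 features dimmest on littermates, 1.68% of model values were at the floor, on at most 3 model arrays in a feature, against 98.8% in these 18. Those 3542 are the dimmest 10% of features above the floor on every littermate, with the 18 left out. They were measurable on littermates by that choice, so they cannot show how a signal that is absent would read. Of all 3718 floor values, 2825 lay in features whose median above the floor was under 20. Array medians were 18.9, so a large part of all features lies under 20 as well. Independent loss of unrelated transcripts is argued against by their placement, with 8 pairs in consecutive rows where the highest of 100000 random draws had 2 (permutation p 1e-05, the smallest these draws can give). A placeholder is a candidate explanation that no test here addressed directly. The single model value above the floor among the bright ones of these features was 3.32, also far below the littermates. Handling of arrays in separate sets may play a part, since 114 features were above the floor on littermate 3 alone. Why these 18 positions follow the genotype stays open; of the 2168 features with a floor value, 1859 had it on 1 array alone.

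The 6 called features above the floor could reflect the genotype or a set of arrays. The sets were taken as the genotype groups, and floor positions only split off littermate 3 as its own. With these sets as a random block and floor features left out, limma called 0 features (smallest adjusted p 0.0695; 2452 at an unadjusted p under 0.05), against 0 without the block (2129) and 69 with array weights (3262). With all features kept, the block called 8 above the floor. Neither count separates set from genotype. By that definition the model arrays form 1 set, littermates 1 and 2 another and littermate 3 its own. No set could hold both groups, so both explanations cannot be told apart. The estimated correlation within sets was -0.0255.

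Other splits of the 12 arrays into 9 and 3 were counted over 100 splits, the real one included. As many as the real 20 calls came from 3 splits, with 135 as the highest of the others, and as many as the real 6 above the floor from 4 splits, again with 135 as the highest. Features without overlap above the floor numbered 585 in the real split, 3 splits gave as many, and the highest other gave 976. With array weights and floor features left out, the real split called 69, 4 splits called as many, and the highest other called 323. Over all 220 splits, 3 gave as many features without overlap (1.36%) and 7 as many weighted calls (3.18%, highest other 737). Both shares are under 0.05, which argues against a random split as the source of these counts. With no correction for the number of counts examined, this does not exclude chance. Chance is also not excluded for the 20 and 6 calls, since the floor features follow the real groups and raise the counts of that split. Nor is it excluded for the 2129 features at an unadjusted p under 0.05, since 11 of the 100 splits and 14 of all 220 gave as many, and the highest other gave 3203. With floor features left out the real split called 0 in unweighted limma, while 10 others of the 100 splits and 20 of all 220 called at least 1.

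Within the 100 splits the highest other count came each time from the split that sets models 3, 4 and 8 apart, with 180 calls when floor features were left out; the split of models 5, 6 and 7 gave 124. These counts are the highest of many splits, and no counts from arrays without structure were made to set against them. Correlation between features may also raise the counts of a few splits. Whether they reflect a structure among the arrays was therefore not settled. Any such structure need not be confined to the model arrays. Over all 220 splits the highest weighted count, 737, set models 5 and 7 with littermate 3 apart. A single deviating model array is argued against as the whole source of such high counts. With each model array left out in turn, the highest count over the 165 splits of the other 11 arrays was 49 to 204. Without model 7 the first component of the model arrays held 26.6% of their variance, against 15.4% as the highest of 20 shuffles that remove all correlation between features. Any correlation between features raises the first component above such shuffles, so this comparison cannot tell whether model 7 was the whole source. An order of the animals that follows the numbers in the titles may play a part and stays open. Distance between model arrays correlated with the difference of those numbers at r = 0.189 (permutation p 0.128, one-sided, n = 9), and permuted numbers had an SD of 0.164, so the value is too close to the bound of 0.2 to decide. Biological differences between the animals, such as sex, age or disease stage, were not tested.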

How the results depend on the processing

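Settings that leave out or mask floor values, the random block, their combinations with another choice and the settings of the separation were chosen after seeing the data. The main test called 20 features, 6 of them above the floor. Both counts stayed within 1.5 times of these under other dim filters, pseudocount 32, limma without trend or with robust fitting, and the random block. They were also unchanged under quantile normalization, which could change little since the arrays already share 1 distribution. With array weights the counts were 86 and 72, with separate group spreads 35 and 21, with pseudocount 1 they were 1 and 1, and in the exact permutation test per feature 0 and 0; a 2-fold minimum left 2 above the floor. With pseudocount 1 the floor features fall under the dim filter. In the permutation test the smallest p that 220 splits allow cannot pass the adjustment over 21736 features unless many features reach it. The cause was not tested for the weights and the group spreads. With floor features left out or floor values set to missing, limma called 0 (2129 and 2142 at an unadjusted p under 0.05). With floor features left out it called 69 with array weights, 4 with separate group spreads and 0 with the block.

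Leaving out each array in turn gave 14 to 35 calls, and 0 to 21 above the floor. The count above the floor was 21 without model 1, 13 without model 9, 3 without model 5, 2 without model 6 or model 7, 1 without model 4 and 0 without littermate 2. With floor features left out the same gave 0 to 6 calls: 6 without model 1, 3 without model 9, 2 without littermate 1 and 0 without each of the others. All 4 named features kept their direction in each of 41 alternatives. No setting here could readily reverse it, since the groups do not overlap in any of these 4 features. Their call was kept in 24 for feature 31720, 16 for feature 35231, 16 for feature 1464 and 15 for feature 7890. Leaving out any 1 littermate, floor features kept, ended the call of all 4, with adjusted p of 0.0570, 0.110 and 0.108 for feature 31720 without littermates 1, 2 and 3. Over all alternatives adjusted p ranged from 0.00285 to 0.356 for feature 31720. The difference in median SD between model and littermates, 0.0498 from groups of unequal size, was 0.0342 without the dim filter. The pseudo-F with floor features left out, 1.62, was highest without model 9 at 1.76. Its exact permutation p, over the fewer splits that remain, was 0.05 or more without littermate 1 (pseudo-F 1.31), littermate 2 (1.32), littermate 3 (1.38), model 2 (1.52) or model 4 (1.51). Gene lists, Gne, the mean of a gene's features and the sex term were not run, since rows have no gene names. Signal over background is unknown, so the dim filter stands in for detection.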

Other observations

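The test against the numbers in the titles was applied to single features only after their values were seen. Feature 16116 stood at an intensity of 557 to 602 on models 2, 3 and 4 and littermate 1, and at 26.3 to 44.8 on the other 8 arrays. The titles of those 4 arrays carry the consecutive numbers 252 to 255. Only splits with at least 2 arrays on each side were counted, and 11 features above the floor had such a split with a gap of at least 2-fold. In 5 of them the arrays of the smaller part were next to each other in the order of the title numbers. If features were independent, 1.14 would come by chance. Of those 5, 3 were high on models 6 and 7 alone, so they are not independent. Neither feature 16116 nor the other 10 separate model from littermates.

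Over all rows, 10 runs of neighbouring rows, with 325 features and including the 4 that hold bright floor features, had bright and nearly constant values, and their starts lay 3577 to 3668 rows apart. On littermate 3, the highest of the values that were above the floor on that array alone was 1417, and 19 features with a median of at least 100 were at the floor on it alone.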
